A study of Arabidopsis thaliana with 2 samples.

How the data were processed

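Total RNA from whole Arabidopsis thaliana plants was hybridised, as biotin-labelled cRNA, to ATH1 arrays, a 1-colour Affymetrix platform on which each transcript is read by a set of short probes. The labels describe 1 array of the mutant line axr4-2 and 1 array of wild-type Col0, both with 24 h of light per day at 22 °C. The growth stage is labelled 1.02 for both, but the source names carry a further, unexplained code that may describe the plants' age, so the stage is uncertain. RNA was extracted with a column kit, per the labels' protocols. Group membership was taken from the sample labels. With 1 array per group no test, SD between replicates or p-value was possible, and the number of arrays limits the precision of every value.

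The deposited values are intensities on a linear scale, 1 per probe set, for 22810 probe sets on each array. The mean after trimming 2% at either end was 100 on both arrays, as a scaling of each array to a common target would leave it. The software and background method behind these intensities are not given in the sources used here. Scan background, per the labels, averaged 70.79 on the axr4-2 array and 80.02 on the wild-type array, with noise of 3.96 and 5.69.

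Probe sets were named from the platform annotation through its gene identifiers. It gave 1 gene for 13513 probe sets and several genes for 503, while 8794 probe sets, 64 control probe sets included, are unnamed here. Of the 13513, 13436 matched the RefSeq gene table of assembly TAIR10.1, which was used for names only, and 77 kept the annotation's own identifier. No probe set was named for AXR4, the mutated gene, which is not analysed here. Of the 391 genes in the lists fixed beforehand, 58 had a named probe set and 33 of these were measured, so that many well-known auxin genes are not analysed here either.

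Each value was raised to the 25th percentile of its array where it lay below, and the log2 ratio of axr4-2 over wild type was taken. A gene was represented by its brightest probe set, and counted as measured when its higher value reached the 50th percentile of its array, which 6381 of 13355 named genes did. Genes with a log2 ratio of 1 or more, or of -1 or less, were counted as 2-fold or more apart. A ratio with one value at the floor is a lower bound. Genes named in the text are the 12 highest and 12 lowest log2 ratios among genes whose higher value reached the 60th percentile, the 2 highest and 2 lowest measured members of each gene list, and any measured member of the lists for early auxin-induced genes, auxin transport and root hairs. Exceptions are stated.

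The median log2 ratio of a gene list with at least 3 measured members was placed among the medians of 10000 random lists of the same size, drawn from the other measured genes and matched on mean log2 intensity in 20 bins. A list was said to stand apart at percentile 99 or above, or 1 or below. This describes these 2 arrays and is not a test of genotype. The ratio threshold, filters, naming rule, alternatives and 24 gene lists were fixed before the data were examined. Because few of those genes could be named, 32 further lists, mostly gene families, were written after the annotation and the control probe sets had been seen, and before any gene's ratio was computed. The result of 1 added list is not reported here.

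The steps were tested on simulated data for axr4-2 against wild type, in which the 6381 measured genes carried shuffled ratios. Of 100 genes given a log2 change of 1.5, 86% were 2-fold or more apart, against 100% of 100 genes given 2.5 and 2.35% of 6181 unaltered genes. Unaltered genes carried the observed ratios, so their share follows from the observed share and is no error rate. Of 300 unaltered lists of 12 genes, 1.67% stood apart, against 49% of 100 lists shifted by 0.3 and 99% of 100 lists shifted by 0.6. Shuffling removed any variation shared within a family, so the 1.67% may not hold for real families. Unaltered lists were counted on both sides and shifted lists on the high side only. Fewer random lists were drawn here than for the real data. Alternatives covered the scaling between the arrays (median centring, quantile normalization, removal of a lowess trend with a span of 0.3), the floor, the filter on dim genes and the choice of probe sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.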

Results

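The series set the transcript profile of axr4, an auxin-resistant mutant, against that of the wild type. AXR4 is a protein of the endoplasmic reticulum that is needed to bring the auxin influx carrier AUX1 to the plasma membrane; the AXR4 transcript itself is not analysed here, so the mutant label was not checked against it. The data are 1 array of whole axr4-2 plants and 1 array of whole Col0 plants. There are no replicates, so no difference given here has a replicate check. "Higher" and "lower" describe the axr4-2 array relative to the wild-type array, and gene values are the deposited intensities.

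Most genes had similar intensities on both arrays. Of 6381 measured genes, 60 were 2-fold or more higher in axr4-2 and 94 were 2-fold or more lower, while 6227 lay between. The median log2 ratio was -0.04 and its SD across genes 0.41. The split depended on scaling: quantile normalization gave 76 higher and 70 lower, and removal of the signal-dependent trend gave 106 higher and 51 lower. Bacterial spike-in probe sets, which read RNA added in fixed amounts, had a mean log2 ratio of 0.09 with an SD of 0.18 over 18 probe sets. In 30 genes with a second measured probe set, the ratios of the pair implied an SD of 0.40 for a single probe set, and 4 of these genes differed 2-fold or more between their own probe sets. The pair had the same sign in 19 of the 30 genes. The SD of 0.40 was about as large as the SD of 0.41 across genes.

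The 12 highest ratios belonged to genes of various functions, and no shared function was tested among them. AT1G06000, a flavonol rhamnosyltransferase, read 224.2 in axr4-2 and 39.3 in wild type, a log2 ratio of 2.51. UGT78D1, which adds rhamnose to flavonols at another position, read 108.7 and 40.2 (1.44). The subtilisin-like protease gene AT4G30020 read 112.1 and 22.1 (2.34), the cysteine protease gene AT2G27420 read 107.5 and 26.1 (2.04), and the pectate lyase gene AT1G67750 read 69.6 and 25.7 (1.44). AT1G13730 read 62.3 in axr4-2 and lay at the floor in wild type, so that it was at least 4.61-fold higher. The chloroplast genes psaA, which encodes a core subunit of photosystem I, and psbN were higher as well, with log2 ratios of 1.65 and 1.91. They were the only 2 of 33 measured chloroplast-encoded photosynthesis genes to be 2-fold or more higher. The median of the 33 was -0.02, and psaB read 3037 and 3050 (-0.01). The remaining genes among the 12 highest were AT5G02890 (1.93), AT5G41400 (1.79), AT4G26480 (1.77) and the U-box ligase gene PUB49 (1.67). With the floor at the 40th percentile, AT1G13730, AT5G02890, AT4G26480 and PUB49 shrank to log2 ratios of 1.11, 1.06, 1.18 and 1.06. Wild-type values of these genes and of AT4G30020, AT2G27420, AT1G67750 and AT5G41400 lay below the brightest Bacillus control probe set on that array (27.1). The size of their ratios is therefore uncertain.

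The 12 lowest ratios were likewise not tested for a shared function. AT4G27654 read 14.4 in axr4-2 and 66.9 in wild type, a log2 ratio of -2.22 that shrank to -1.38 with the floor at the 40th percentile. The 14.4 lay below the brightest Bacillus control probe set on the axr4-2 array (18.1), so the size of this ratio is uncertain. AT1G33055, one of the genes that plants induce under low oxygen, read 82.3 and 284.7 (-1.79). AT4G15690 and AT4G15700, neighbouring genes for CC-type glutaredoxins, had log2 ratios of -1.77 and -1.52. GAT1_2.1, which encodes a glutamine amidotransferase, read 42.5 and 126.9 (-1.58). The others among the 12 lowest were AT5G40490 (-1.69), AT1G11540 (-1.67), AT4G37220 (-1.62), AT1G15010 (-1.62), AT3G24250 (-1.57), AT1G19170 (-1.53) and AT1G12790 (-1.51). Among probe sets unnamed here, 61 were 2-fold or more higher and 70 lower.

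**Figure D1:**
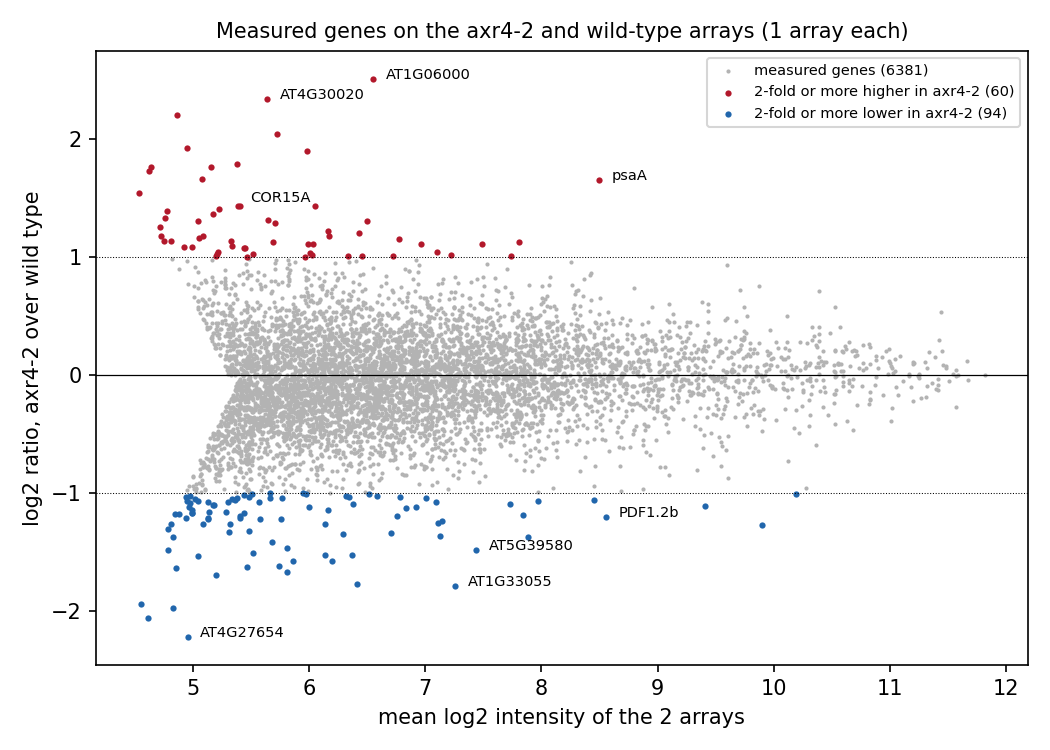
Log2 ratio of axr4-2 over wild type (vertical axis) against the mean log2 intensity of the 2 arrays (horizontal axis), 1 point per measured gene, with dotted lines at 1 and -1. The 60 genes at 1 or above and the 94 at -1 or below lie mostly at low intensity, with psaA and PDF1.2b among the brighter exceptions.

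Early auxin-induced genes were lower in axr4-2 in all 4 measured cases. IAA29, an Aux/IAA repressor gene, read 22.5 in axr4-2 and 46.6 in wild type (-1.05). GH3.5, whose product conjugates auxin to amino acids, read 103 and 153.9 (-0.58). HAT2, an auxin-induced homeodomain gene, read 173.6 and 239.7 (-0.47), and LBD16, which acts in lateral root initiation, read 42.6 and 55.4 (-0.38). Their median of -0.52 lay at percentile 2.85 of random lists and did not stand apart; with the signal-dependent trend removed it reached percentile 1.00, while the ratio of the dim IAA29 shrank to -0.64. With no filter on dim genes the list held 10 members, and its median of -0.17 lay at percentile 42.9. That median is the ratio of the 2 floors, taken by GH3.1, IAA20 and LBD29 with both values at the floor. It therefore measures no auxin gene. Among members left out by the filter, GH3.3 read 39.4 and 37.9 (0.06), just below the axr4-2 array median of 39.5. SAUR10 (15.8 and 14.4, 0.13) was also slightly higher, and IAA30 lay at -0.04 with its wild-type value at the floor. The direction shared by all 4 measured genes thus depends on the filter. Of other auxin lists, IAA18 (-0.07) and the auxin synthesis gene YUC2 (-0.25) were the further measured members; no gene of the auxin transport list was measured.

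Cell wall loosening genes stood apart on the high side, with a median of 0.60 at percentile 99.9. The expansin genes EXPA8 (459.7 in axr4-2 and 254.4 in wild type, 0.85) and EXPA4 (0.77) were higher, as was XTH19 (0.43), while XTH18, its neighbour that also encodes a xyloglucan-modifying enzyme, was lower (-0.73). With the filter at the 75th percentile of intensity, 3 members were left and the list no longer stood apart (0.43, percentile 97.4). The wider expansin family, which includes EXPA4 and EXPA8, had 9 of 11 measured members above 0 and a median of 0.31 at percentile 99.7. EXPB3 was 2-fold or more higher (163.4 and 73.2, 1.16) and EXLA1 2-fold or more lower (145.1 and 309.7, -1.09). Without the filter on dim genes the family fell short of standing apart (0.11, percentile 98.6).

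Class III peroxidases, secreted enzymes that act on wall polymers and reactive oxygen, were higher as a family. Of 31 measured members, 22 lay above 0, and the median of 0.34 exceeded those of all 10000 random lists, at percentile 100. Over all 55 named members, with no filter on dim genes, the median was 0.06 at percentile 99.99. AT2G18980 (196.5 in axr4-2 and 95.4 in wild type, 1.04) and AT4G30170 (302.4 and 150.4, 1.01) were 2-fold or more higher. AT5G39580 went the other way (103.9 and 289.3, -1.48), as did AT2G39040 (-0.72).

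Extensins, hydroxyproline-rich structural wall proteins, were lower in all 6 measured cases, with a median of -0.71 at percentile 0.08. AT5G06630 read 89.6 in axr4-2 and 184.8 in wild type (-1.04), and AT3G54580 read 22 and 44.8 (-1.03, and -0.59 with the trend removed). AT1G23720 (-0.52) and AT4G08410 (-0.55) were closest to 0. Of the 6 genes, 4 were read by probe sets shared between transcripts, so these values are not independent of one another. The root hair expansin genes EXPA7 (41.8 and 51.3, -0.30) and EXPA18 (54.1 and 51.9, 0.06) were the measured members of the root hair list.

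Genes for cytosolic ribosomal proteins and for tubulins were slightly higher. Of 100 measured genes for cytosolic ribosomal proteins, 86 lay above 0 and none was 2-fold apart; the median was 0.16, at percentile 100. The ends of the family were AT5G15520 (0.72) and AT3G16780 (0.64) against AT4G34555 (-0.22) and AT5G27770 (-0.18). Tubulin genes had 6 of 7 measured members above 0 and a median of 0.48 at percentile 99.99, with TUB7 (321.4 and 204.1, 0.66) and TUB9 (0.58) highest, and TUA1 (-0.13) and TUB5 (0.14) lowest. The cell cycle gene MCM7 read 106 and 71.8 (0.56), whereas the 6 measured of 31 listed core histone genes had a median of 0.01 at percentile 55.1.

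Markers of shoot tissue were nearly equal. The photosynthesis genes RCA (0.08), PRK (0.11) and LHCB4.1 (0.12) had a median of 0.11 at percentile 76.4, and 24 nuclear-encoded photosynthesis genes, which include these 3, had a median of 0.03 at percentile 50.6 that turned to -0.01 under quantile normalization. PYK10, an abundant beta-glucosidase of roots, read 2982 and 2967 (0.01), a direction that also turned with scaling (-0.04 under quantile normalization). The 33 chloroplast-encoded photosynthesis genes had a median of -0.02 at percentile 19.4, which median centring turned to 0.02, although psaA and psbN were 2-fold or more higher. The 17 chloroplast genes for ribosomal proteins and RNA polymerase subunits had 13 members below 0 and a median of -0.16 at percentile 1.1, led by rpoC2 (192.1 and 326.4, -0.76) and rps14 (-0.67). They passed percentile 1 with quantile normalization (0.6), with the trend removed (0.74) and with the filter at the 75th percentile of intensity (0.42).

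Stress and hormone genes were mixed. All 4 measured genes of the abscisic acid and cold list were higher: the cold-regulated COR15A read 68.8 and 25.5 (1.43), the dehydrin gene COR47 read 898.6 and 650.8 (0.47), and LTI30 (0.24) and COR15B (0.23) were closer to 0. The median of these 4 genes was 0.35, at percentile 98.8. The wild-type value of COR15A lay below the brightest Bacillus control probe set on that array (27.1), so the size of its ratio is uncertain. The flavonoid list had a median of 0.47 at percentile 98.7, from UGT78D1 (1.44), UGT78D2 (173 and 111.5, 0.63), DFR (0.30) and UGT79B1 (-0.49). Neither list stood apart. The jasmonate-responsive defensin gene PDF1.2a read 77.2 and 168.9 (-1.13), and its near copy PDF1.2b 248.5 and 571.2 (-1.20). Defensin-like genes as a family had a median of -0.39 at percentile 0.63 over 6 members, but -0.15 at percentile 18.7 over 5 once probe sets shared between transcripts were left out, and -0.17 at percentile 47.3 with no filter on dim genes. This last median is again the ratio of the floors, taken by members with both values at the floor. Lists with 1 measured member gave the seed storage gene PAP85 (19.4 and 56, -1.53), the oil-body lipase gene SDP1 (96.4 and 162, -0.75), the ethylene signalling gene RTE1 (-0.93), HSA32 (-0.40), ZAT10 (0.24), GI (0.05) and BHLH101 (-0.07, and 0.00 with the trend removed). The ratio of PAP85 shrank to -1.12 with the floor at the 40th percentile. Its axr4-2 value lay just above the brightest Bacillus control probe set on that array (18.1), so its size is uncertain.

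Over all lists, 33 had 3 or more measured members and 8 stood apart, 6 higher and 2 lower, where separate lists of unrelated genes would give 0.66 by chance. The 8 are not separate results: cell wall loosening genes and expansins share EXPA4 and EXPA8. Of the 6 measured extensins, 4 were read by shared probe sets. Cell wall loosening, expansin, defensin-like and serine carboxypeptidase-like genes each lost their place under some alternative settings. Of the 8, 1 belongs to the lists fixed before the data were examined and 7 to those added later. Genes of a family that are regulated together may vary together between any pair of plant samples. The random lists do not reproduce such variation, and it was not measured here.

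RNA quality probe sets differed between the arrays. The signal of 3′ over 5′ probe sets, which rises as RNA is degraded, was 2.12 in axr4-2 and 3.23 in wild type for actin, 1.05 and 1.03 for GAPDH, and 1.81 and 2.26 for ubiquitin. Older probe sets on the array gave 1.27 and 2.14 for GAPDH and 2.36 and 3.71 for ubiquitin, but 7.78 in axr4-2 and 4.08 in wild type for actin. The ratio was thus higher in wild type in 4 of the 6 pairs. Levels of these probe sets were mostly higher in axr4-2. The newer ones had log2 ratios of 0.42, 0.64 and 1.03 for actin (3′, middle and 5′). They had 0.50 and 0.47 for GAPDH and -0.01 and 0.31 for ubiquitin (3′ and 5′). Of the older ones, actin 5′ (-0.52), ubiquitin 3′ (-0.28) and GAPDH 3′ (-0.04) were lower. Whether these differences bear on the list medians above was not tested.

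**Figure D2:**
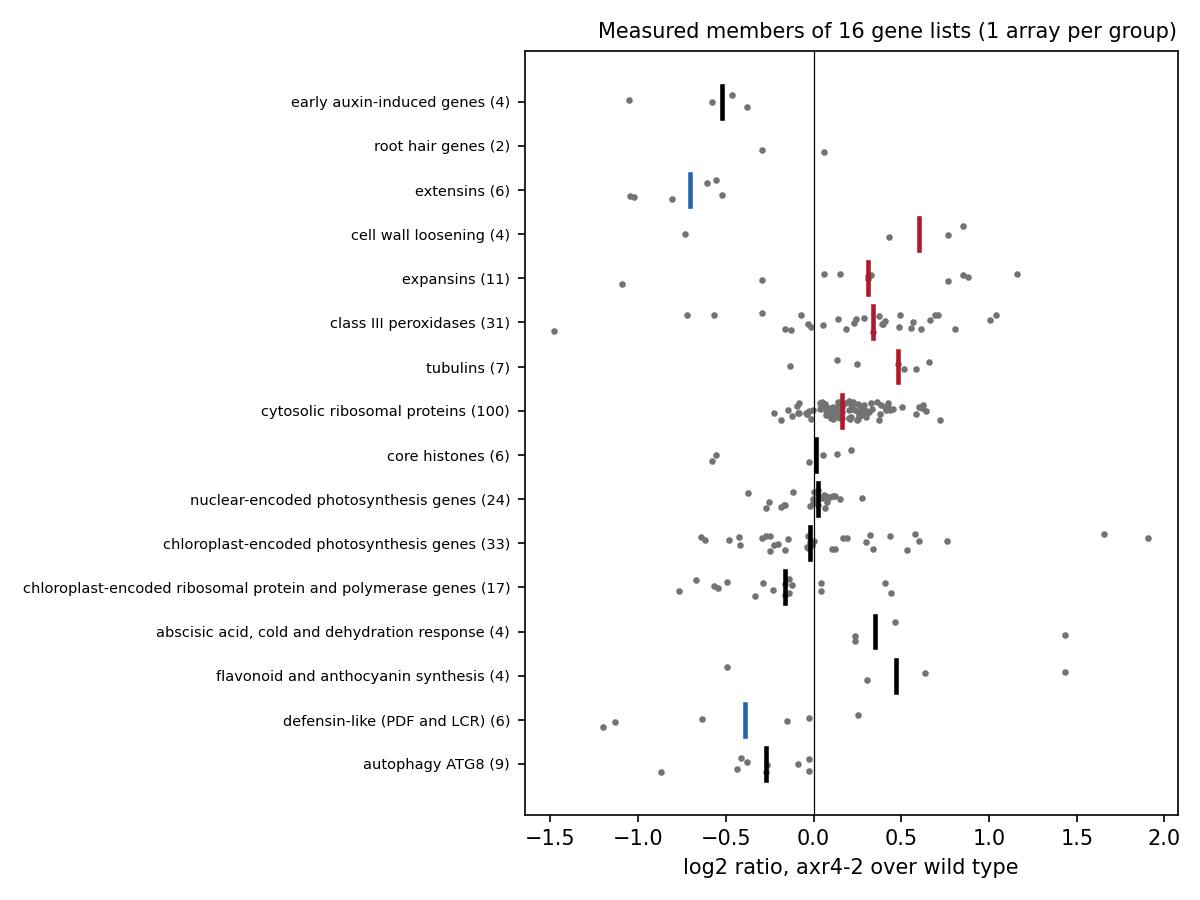
Log2 ratio of axr4-2 over wild type (horizontal axis) for the measured members of 16 gene lists, 1 point per gene, with the number of members in brackets. Vertical bars are list medians for lists with 3 or more members, red where the list stood apart on the high side, blue on the low side and black otherwise; the 6 extensins lie below 0 and most of the 31 class III peroxidases above it.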

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

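Means in place of medians, and all alternatives for the added lists, were chosen after seeing the data files. The count of genes 2-fold or more higher, 60, became 106 with the lowess trend removed, 99 with no filter on dim genes and 16 with the filter at the 75th percentile; the 94 lower genes became 51, 226 and 31. The filters act through the number of genes counted (13355 and 3083); with no filter, genes with both values at the floor take the ratio of the floors, -0.17. That ratio is also the no-filter median of all genes and of early auxin-induced and defensin-like genes. The lowess setting kept 59 of the 60 higher and 50 of the 94 lower genes. Across lists, 276 of 290 alternative medians kept their side of the percentile threshold, and the mean had the sign of the median in 28 of 33 lists, those standing apart included. Many of the 290 could hardly change. Median centring shifts all genes alike, so percentiles stay the same, and most lists hold no shared probe sets to leave out. The 276 therefore overstates how stable the lists are. Early auxin-induced genes came to stand apart with the trend removed (-0.51), as did chloroplast ribosomal protein and polymerase genes with quantile normalization (-0.21), the trend removed (-0.18) and the 75th percentile filter (-0.16). With no filter, the TBL family (0.13) came to stand apart on the high side. UDP-glycosyltransferases (-0.16) reached percentile 99.1 beside the floor ratio, which shows no rise. Expansins (0.11) and defensin-like genes (-0.17) lost their place. So did cell wall loosening genes at the 75th percentile filter (0.43) and defensin-like genes without shared probe sets (-0.15, 5 genes). Serine carboxypeptidase-like genes (0.25 as reported) lost their place with quantile normalization (0.23), the trend removed (0.25) and the 75th percentile filter (0.25). With no filter they also lost it, and the sign turned beside the floor ratio (-0.17, percentile 81.3). Beyond changes in the genes counted, the cause was not tested. Of 1375 alternative values of named genes, 12 moved by more than the SD of 0.40 for a single probe set and none 2-fold or more apart changed sign. Median centring moved every named gene by the same amount, below that SD, so it could add none of the 12. In 7 cases a list kept under 3 members and gave no value. Alternatives for AXR4 were not run. With 1 array per group, leaving out an array and a paired analysis were impossible. Signal over background limits the dim genes most: 27 control probe sets for Bacillus and tryptophan genes averaged 3.17 in axr4-2 (highest 18.1) and 3.06 in wild type (highest 27.1), so that the dimmest named values, such as 14.4 for AT4G27654 in axr4-2, lie within the range of these controls.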

Other observations

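Further families showed small shifts that did not stand apart, apart from serine carboxypeptidase-like genes, whose median of 0.25 lay at percentile 99 over 12 members, with SCPL46 at 1.03 and SCPL34 at -0.55; its dependence on settings is given above. All 9 ATG8 genes, which encode the ubiquitin-like proteins of autophagosome membranes, lay below 0, with a median of -0.27 at percentile 1.73. ATG8E was the lowest (578.2 in axr4-2 and 1056 in wild type, -0.87), while the values of ATG8A (-0.03) and ATG8G (-0.02) changed sign with median centring. The TBL family of wall polymer acetylation had a median of 0.21 at percentile 98.1, with TBL36 at 0.57 and TBL23 at -0.75. GH9 glucanases (0.26, percentile 97.1; GH9C2 at 0.93) and RALF peptides (0.28, percentile 96.6; RALFL27 at 0.80) also lay on the high side, as did tau glutathione transferases (0.20, percentile 94.9), with GSTU25 at 1.13. UDP-glycosyltransferases had a median of 0.04 at percentile 83.5, with UGT76B1 at 1.31 beside UGT78D1. The ER body list (-0.02, percentile 35.9), beta-glucosidases (-0.15, percentile 22.8), SWEET transporters (-0.15, percentile 13.6) and tetraspanins (-0.21, percentile 13) were nearer the middle. So were XTH genes (0.13, percentile 76.2), CYP71B genes (-0.09, percentile 40.7, and 0.01 under quantile normalization), calmodulin-like genes (-0.28, percentile 21) and mitochondrion-encoded genes (-0.16, percentile 28.2). Chloroplast ndh genes (-0.14, percentile 4.21; ndhF at -0.48 and ndhH at 0.87) and plant U-box ligases (0.40, percentile 97.8) lay farther out, and the sign of the ER body median turned with median centring (0.02).

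Genes induced by low oxygen were listed after the low values of AT1G33055 and AT1G72060 (147 in axr4-2 and 379.4 in wild type, -1.37) had been seen. Without those genes, the 7 other measured members had a median of -0.36 at percentile 3.14. Of the 7, AT4G27450 was the lowest (461.4 and 995.3, -1.11) and AT5G66985 the highest (59.1 and 27.7, 1.09); all members of this list are named by choice after their values were seen.

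All tests of explanations below were chosen after the result each concerns was seen. In addition, genotype, plant batch and hybridisation differ together between the 2 arrays, so none of them can be told apart for any pattern, and the effect of the axr4-2 genotype stays open throughout.

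The first pattern is the higher level of cytosolic ribosomal protein genes. A signal-dependent difference in scale between the arrays is argued against by the percentile of 100 itself, because the random lists were matched on intensity. Removing the lowess trend left the median at 0.15 and percentile 100, against an SD of 0.02 for random lists. That adds no separate check, since the matching already covered such a trend. More dividing tissue in the axr4-2 sample could contribute. Core histones had a median of 0.013, below the ribosomal median by less than the SD of 0.15 for random lists of 6 genes. Only these 6 of 31 listed core histone genes were measured, and those with a symbol were all HTB genes. Outside this comparison, tubulins (median 0.48, percentile 99.99) and the 1 measured gene of the cell cycle list, MCM7 (0.56), were higher. More dividing tissue therefore stays open.

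The second pattern is the lower level of CC-type glutaredoxins, a class listed after the values of its chromosome 4 members had been seen. AT4G15660 (-1.35), AT4G15680 (-1.19), AT4G15690 and AT4G15700 lie next to one another or nearly so, and similar copies may hybridise to one another's probes. Of the 10 measured glutaredoxins, 0 were read by probe sets shared between transcripts. That goes against such hybridisation but does not measure it. The 6 measured members elsewhere had a median of -0.28 at percentile 13.5, with AT2G30540 at -0.63 and AT1G06830 at 0.09. The median of these 6 neither shows a shift of the whole class nor excludes cross-hybridisation among the neighbouring copies.

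The third pattern is that extensins were lower while class III peroxidases and expansins were higher. A larger share of root tissue in the axr4-2 sample could raise peroxidases, and stays open. PYK10, with a log2 ratio of 0.0073 beside the peroxidase median of 0.34, was the 1 measured member of the root marker list. That list leaves out root hair genes, of which EXPA7 (-0.30) and EXPA18 (0.06) were measured and were not raised as the peroxidases were. These genes are too few to decide. Shoot markers showed no fall. The 24 nuclear-encoded photosynthesis genes had a median of 0.03 at percentile 50.6, with an SD of 0.05 for random lists. How far a changed root share would lower them was not estimated. For the peroxidases, a signal-dependent difference in scale is argued against by their percentile of 100 among random lists matched on intensity. Their median of 0.40 after the trend was removed adds no separate check. Fewer root hairs in axr4-2 could lower extensins, but the 2 measured root hair genes, with a median of -0.12, are too few to decide. Cross-hybridisation among extensins also stays open, because probe sets for 1 gene read only 2 of them.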
